A study of Homo sapiens with 42 samples.

How the data were processed

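Messenger RNA was measured in MiaPaCa-2 and PANC-1 cells grown without a statin or with fluvastatin, lovastatin or simvastatin at 2 or 20 µM. Per the labels' protocols, total RNA was extracted from harvested cells, mRNA was captured on poly-T beads and primed with random hexamers, and the libraries were sequenced paired-end on an Illumina instrument. The length of the treatment and the vehicle given to the control cells are not given in the sources used here. Per the submitters' processing notes, TopHat2 2.0.13, Cufflinks 1.1 and Cuffdiff were used with the hg19 build. The authors deposited 1 table of log2 FPKM values (fragments scaled to transcript length and to mapped fragments) for 8738 genes and 42 libraries, with an Ensembl ID and a symbol for each gene. In the deposited table the FPKM values ran from 0.00424 to 12.7713 on the log2 scale with 0 values at or below 0, so they were read as log2(FPKM + 1), a pseudocount that no source used here states. In the columns that were not weighted sums of others, at least 98.7% of the values recurred in 5 or more columns, as they do in a table whose libraries were scaled to a shared distribution, and that step is not given in the sources used here. No raw counts were used, so the depth of each library is unknown, and no interval or floor that needs it is given. Gene coordinates are not printed.

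The rule by which the 8738 genes were chosen is not given in the sources used here, and the table held few genes that stayed level. An ordinary analysis of variance across the 7 groups of a line was run for each of the 8738 genes, without the expression filter. In it, 88.3% of the genes in MiaPaCa-2 and 80.1% in PANC-1 had an unadjusted p under 0.05, and 212 and 411 genes had a p above 0.5. Shares of genes called and adjusted p-values therefore hold for this table and not for all expressed genes. There were 7 symbols held by 2 gene IDs, which were kept apart by ID.

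A check of the columns against each other found 2 derived columns. The column labelled MiaPaCa-2 control 3 equalled 0.5 times control 1 plus 0.49 times control 2 plus 0.01 times PANC-1 fluvastatin 20 µM replicate 2. The column labelled MiaPaCa-2 lovastatin 20 µM 3 equalled 0.45 times replicate 1 plus 0.48 times replicate 2 plus 0.07 times MiaPaCa-2 simvastatin 20 µM replicate 3. The largest residual of either sum was 5.00e-09 on the log2 scale. Neither column was used as a replicate, which left 19 independent libraries in MiaPaCa-2 and 21 in PANC-1, and all 42 columns were used as an alternative. All columns were matched to a sample, with 0 left over.

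Libraries were grouped by line, statin and dose from the sample titles, giving 14 groups of 3 libraries by the labels. Genes with an FPKM of at least 1 in at least 3 libraries of a line were tested, 8534 in MiaPaCa-2 and 8615 in PANC-1, and 8738 were tested in a joint fit of both lines. The log2(FPKM + 1) values were fitted with 1 mean per group in limma 3.58.1 under R 4.3.3, with a moderated variance that followed the mean expression and was robust to outlying genes. The contrasts were each statin and dose against the control of its line, 20 against 2 µM averaged over the statins, each pair of statins at the same dose, and the difference between the lines in each response. Benjamini-Hochberg adjustment ran over the genes tested in a contrast, and a gene was called at an adjusted p under 0.05, two-sided. Calls with at least a 2-fold change were counted beside them. Confidence intervals of differences between statins are 95% intervals from the same model.

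Of 32 gene lists, 27 had at least 3 measured members and were tested with camera in limma, with the preset correlation of 0.01 and with a correlation estimated from the residuals, adjusted over the lists of a contrast. The lists held 471 different genes, of which 355 were in the table. Testing the lists on the difference between the lines was added after the data were seen. Mitochondrially encoded mRNAs, endothelial markers, and acinar and islet markers are not analysed here. Fibroblast and leukocyte markers had 2 genes each in the table and were not tested as lists. The genes named were set by rule. They were, for each line and dose, up to 10 genes with the largest mean increase and up to 10 with the largest mean decrease over the 3 statins, among genes called the same way for all 3 and with a group mean of at least 5 FPKM in the control or in every statin group. Further genes were up to 4 members of each list described and up to 5 genes per direction for dose, statin pairs and the difference between lines. The values of CXCL8 against the control at 20 µM in PANC-1 were added after they were seen. Some genes that the rule gave, and 1 tested list, are not reported here. The contrasts, filter, lists, rule for names and most alternatives were chosen before the data were examined.

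The alternatives were a pseudocount of 0.1, no filter, quantile normalization of the table, a replicate block, fits of the 2 compared groups alone, and leaving out each library in turn. Chosen after the data were seen were the fit of all 42 columns and a fit without 2 PANC-1 libraries that stood apart from their groups, control replicate 3 and simvastatin 20 µM replicate 3. MiaPaCa-2 fluvastatin 2 µM replicate 1, which had as many genes at least 2 log2 units below both other replicates as the latter, was left out only by itself. Residuals of libraries with the same replicate number in different groups correlated at between -0.03 and 0.04 in MiaPaCa-2 and between -0.09 and 0.15 in PANC-1, so the numbers were not used to pair libraries.

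The steps were tested on simulated data with 200 changed genes, drawn from genes whose mean on the log2 scale was at least that of 5 FPKM. Recovery was not measured for tested genes below that level. Genes changed 2-fold were recovered at 87% for fluvastatin at 2 µM against control in MiaPaCa-2 (8506 genes) and 94% in PANC-1 (8592 genes), and genes changed 1.5-fold at 44% and 68%. The shares recovered at 2-fold and 1.5-fold were 82% and 50% for lovastatin at 20 µM in MiaPaCa-2 (8508 genes), where both groups held 2 libraries, 86% and 65% for simvastatin against lovastatin at 2 µM in PANC-1 (8590 genes), 97% and 88% for 20 against 2 µM in PANC-1 (8595 genes), and 66% and 31% for the difference between lines with fluvastatin at 2 µM (8738 genes). False calls made up between 4.15% and 12.6% of the calls in these simulations. Of 100 simulated lists without a change, between 1 and 6 had a camera p under 0.05 with the preset correlation. The simulated noise was independent between genes, so this check does not cover lists whose genes vary together.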

Results

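Messenger RNA levels were measured in MiaPaCa-2 and PANC-1, established lines of human pancreatic cancer, grown with a statin or without one. Statins inhibit the synthesis of mevalonate, the precursor of cholesterol and of the prenyl groups attached to many proteins. Fluvastatin is fully synthetic, while lovastatin and simvastatin are lactone prodrugs of fungal origin that differ by 1 methyl group on the side chain ester. Each line had a control group and a group for each statin at 2 µM and at 20 µM, the low and the high concentration of the series. The labels give 3 libraries per group. After removal of 2 columns that were weighted sums of other columns, the MiaPaCa-2 control and MiaPaCa-2 with lovastatin at 20 µM had n = 2, and every other group had n = 3. The table held FPKM on a log2(FPKM + 1) scale, and the depth of each library is unknown. The labels do not say that replicates are separate cultures, so SD and p-values measure only the spread between these samples, which may be technical. "Rose" and "fell" are used for genes with a limma adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes near 0 FPKM.

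The difference between the low dose and the control in MiaPaCa-2 was led by genes of hypoxia and glycolysis, which rose with every statin at 2 µM. Differing controls, and lower oxygen or denser cultures, cannot be told apart from a statin effect here, as set out under the results flagged for a closer look. ANGPTL4, a secreted inhibitor of lipoprotein lipase, had 6.43 ± 0.212 FPKM (n = 2) in the control and 194 ± 6.65, 207 ± 11.2 and 204 ± 4.86 FPKM (n = 3 each) with fluvastatin, lovastatin and simvastatin. NDRG1, a gene induced by low oxygen, went from 9.56 ± 1.32 to 261 ± 41.1, 240 ± 10.3 and 244 ± 5.24 FPKM. VEGFA, which encodes a growth factor for blood vessels, went from 30.4 ± 2.53 to 137 ± 7.07, 170 ± 8.48 and 162 ± 9.99 FPKM. MUC1, a membrane mucin, went from 32.9 ± 12.4 to 727 ± 33.4, 850 ± 126 and 851 ± 71.8 FPKM. Cyclin B1, encoded by CCNB1 and needed for entry into mitosis, fell from 574 ± 37.9 to 318 ± 5.38, 271 ± 13 and 273 ± 3.2 FPKM.

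Averaged over the statins at 2 µM, the largest increases in MiaPaCa-2 were those of ANGPTL4 (log2 fold change 4.77, SE 0.14, adjusted p = 1.7e-13), MUC1 (4.62, SE 0.23, 1e-10), the glycolytic regulator PFKFB4 (4.57, SE 0.15, 9.3e-13), NDRG1 (4.56, SE 0.15, 9.3e-13) and the glycolytic enzyme ALDOC (4.41, SE 0.18, 8.4e-12). PPFIA4, C4orf47, UPK1A, SPAG4 and PTGDS followed, with values between 3.85 and 4.04. The largest decreases were smaller and included MPV17L2, a mitochondrial protein (-1.9, SE 0.16, 1.1e-07), LRP8, a receptor for reelin and apolipoprotein E (-1.7, SE 0.31, 3e-04), the RNA polymerase III subunit POLR3K (-1.54) and RRS1, a ribosome assembly factor (-1.46). Also among them, UBE3D had -1.5, but without control replicate 1 its values were -0.1, -0.35 and -0.32 for fluvastatin, lovastatin and simvastatin and passed no test. Its calls were also lost in fits of 2 groups alone, and with fluvastatin without fluvastatin replicate 1 (-1.2) or 2 (-1.34). WNK2 had -1.47, and its calls were lost with fluvastatin (-0.84) and lovastatin (-1.06) without control replicate 2, and with fluvastatin (-0.88) without fluvastatin replicate 2.

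All 13 measured hypoxia and glycolysis genes rose with each statin at 2 µM in MiaPaCa-2, with median log2 fold changes of 2.13, 2.45 and 2.38 for fluvastatin, lovastatin and simvastatin (camera adjusted p = 2.62e-14, 2.75e-13 and 3.73e-13). Beyond PFKFB4 and NDRG1, the largest changes were those of ADM (mean 3.62) and ANKRD37 (3.51). Of 9 interferon-stimulated genes, 7 rose with each statin, among them IFIT3 (1.28), IFIT2 (1.25) and IFIT1 (1.16), with adjusted p = 0.000304, 0.000277 and 0.000695. Extracellular matrix and integrin genes rose in 8, 6 and 7 of 13, with COL6A2 (2.11) and the crosslinking enzyme LOXL2 (1.45) leading (adjusted p = 0.000688, 0.00598 and 0.00398). DNA replication genes fell in 13, 12 and 15 of 23, led by MCM7 (-1.03) of the replicative helicase (adjusted p = 0.000767, 0.00133 and 0.00159). Mitosis genes fell in 14, 16 and 15 of 20, led by CDC20 (-1.32) and CCNB1 (-1), with adjusted p = 0.000304, 0.000167 and 0.000328; adjusted over the list alone, 15, 16 and 15 fell. The calls of these 5 lists held with an estimated correlation.

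Genes of the integrated stress response rose in 8, 10 and 10 of 18 at 2 µM in MiaPaCa-2, with DDIT4 (mean log2 fold change 2.2), NUPR1 (1.96) and DDIT3 (1.76) among them (adjusted p = 0.0104, 0.00133 and 0.00471). That call held for lovastatin with an estimated correlation (adjusted p = 0.0297) and was lost for fluvastatin and simvastatin (adjusted p = 0.0779 and 0.0616 with an estimated correlation). Cell cycle inhibitors and p53 targets rose in 6, 7 and 7 of 12, including CDKN1A, the inhibitor p21 (1.34), and SESN1 (1.22), with adjusted p = 0.0102, 0.0103 and 0.00398, but adjusted p = 0.15, 0.131 and 0.0915 with an estimated correlation. Kruppel-like factors rose in 5 of 8 with each statin (adjusted p = 0.0164, 0.014 and 0.0284), with adjusted p = 0.0774, 0.0606 and 0.0864 with an estimated correlation. Common reference genes also moved, with PGK1 at 1.94, B2M at 1.34 and GAPDH at 0.56, and the list was called for fluvastatin and simvastatin (adjusted p = 0.0375 and 0.0131, but adjusted p = 0.113 and 0.0644 with an estimated correlation). Cholesterol synthesis genes went both ways. Of 20 measured, 2 rose with each statin and 4, 5 and 6 fell, with TM7SF2 at 1.1 and FDFT1 at -0.86, and the list was not called (adjusted p = 0.49, 0.19 and 0.4).

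In total, 3686, 3881 and 3886 of 8534 genes were called with fluvastatin, lovastatin and simvastatin at 2 µM in MiaPaCa-2, which is 43.2%, 45.5% and 45.5%. Of these, 1782, 1873 and 1855 rose and 1904, 2008 and 2031 fell. At least 2-fold increases were seen for 493, 549 and 546 genes, and at least 2-fold decreases for 119, 189 and 181. The control of this line rests on 2 independent libraries.

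**Figure D1:**
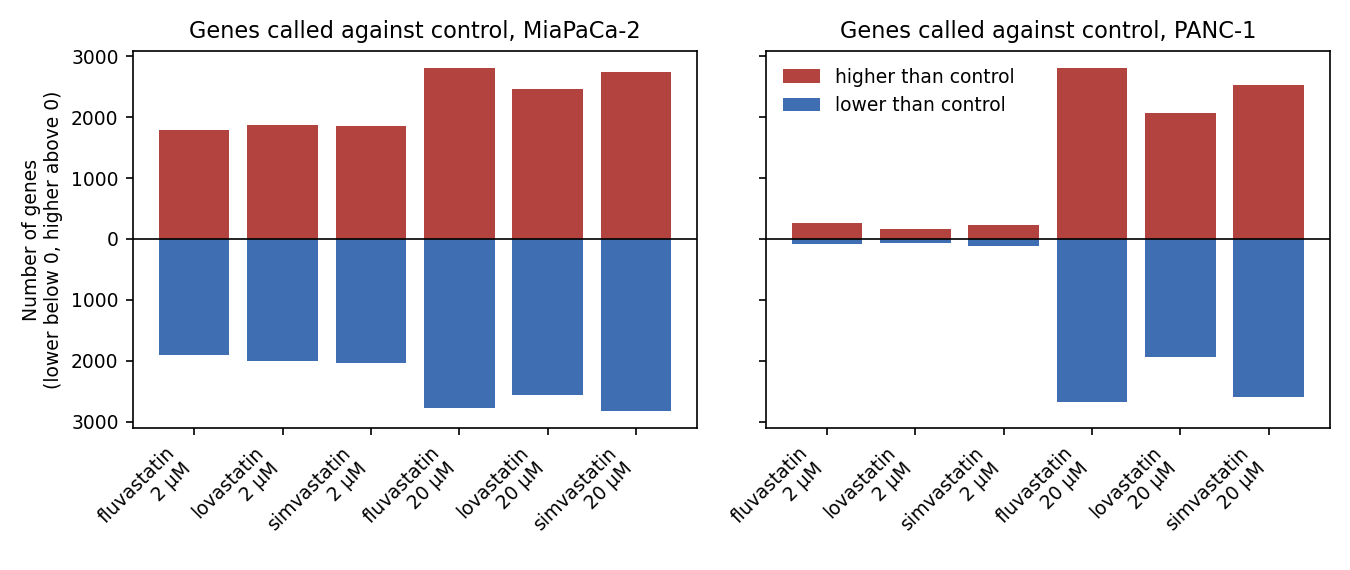
Number of genes called against the control (vertical axis; higher genes above 0, lower genes below 0) for each statin and dose (horizontal axis) in MiaPaCa-2 (left) and PANC-1 (right). In MiaPaCa-2 between 3686 and 3886 genes were called at 2 µM, and in PANC-1 between 242 and 342.

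At the high dose, 20 µM, MiaPaCa-2 cells had much lower levels of the genes of DNA replication and mitosis and higher levels of genes of cell cycle inhibitors and p53 targets, Kruppel-like factors and autophagy. RRM2, the subunit of ribonucleotide reductase that limits deoxynucleotide supply, fell from 312 ± 5.78 FPKM (n = 2) to 8.13 ± 2.88 (n = 3), 24.1 ± 0.844 (n = 2) and 24.1 ± 5.31 FPKM (n = 3) with fluvastatin, lovastatin and simvastatin. TOP2A, the topoisomerase of dividing cells, fell from 183 ± 4.51 to 8.59 ± 1.02, 21 ± 1.41 and 20 ± 3.14 FPKM. KRT16, a keratin of stressed epithelium, rose from 1.41 ± 0.101 to 337 ± 6.45, 175 ± 16.4 and 164 ± 6.74 FPKM. CDKN1A rose from 1.99 ± 0.307 to 35.1 ± 2.62, 45.2 ± 1.01 and 36 ± 2.63 FPKM.

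Among the largest mean increases at 20 µM in MiaPaCa-2 were those of KRT16 (log2 fold change 6.47, SE 0.12, adjusted p = 3.1e-16), the prostaglandin synthase gene PTGDS (5.35, SE 0.16, 7.6e-14), the glucocorticoid-induced gene TSC22D3 (4.94, SE 0.14, 5.7e-14) and the stress transcription factor ATF3 (4.57, SE 0.14, 1.4e-13). PNCK (4.28), NDRG4 (3.94), CDKN1A (3.73) and the autophagy genes ATG9B and GABARAPL1 (3.64 each) followed. The largest decreases were those of RRM2 (-4.15, SE 0.16, 2e-12), the kinetochore gene NUF2 (-3.8), the mitotic kinase PBK (-3.76), the processed pseudogene RRM2P3 (-3.69) and the survival and mitosis gene BIRC5 (-3.6). KIF20A, DLGAP5, SPC24, TOP2A and UHRF1, which serve mitosis or DNA replication, had values between -3.59 and -3.41.

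All 20 mitosis genes fell with each statin at 20 µM in MiaPaCa-2, with medians of -3.54, -2.50 and -2.48 for fluvastatin, lovastatin and simvastatin (camera adjusted p = 1.6e-13, 1.36e-12 and 2.42e-11). Replication genes fell in 23, 21 and 22 of 23, including GINS2 (mean -3), CDC45 (-2.96) and MCM5 (-2.94), with adjusted p = 1.01e-11, 1.62e-10 and 1.52e-09. Cell cycle inhibitors and p53 targets rose in 10, 11 and 10 of 12, including BBC3, which encodes the death-promoting protein PUMA (3.45), and PHLDA3 (2.95), with adjusted p = 5.46e-05, 1.62e-06 and 7.7e-06. Kruppel-like factors rose in 6, 6 and 8 of 8, among them KLF6 (2.74), KLF4 (2.68) and KLF2 (2.61), with adjusted p = 0.000541, 9.94e-05 and 3.02e-05. Autophagy and lysosome genes rose in 10, 8 and 9 of 13, with WIPI1 at 3.16 and SQSTM1 at 2.21 (adjusted p = 0.00988, 0.00157 and 0.00316). The calls of these 5 lists held with an estimated correlation for each statin.

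The lists of the integrated stress response, of NF-kappaB targets and of NRF2 targets were called with lovastatin and simvastatin and not with fluvastatin at 20 µM in MiaPaCa-2. Integrated stress response genes rose in all 18 with simvastatin (median 2.05, adjusted p = 6.64e-12) and in 16 with lovastatin (1.26, adjusted p = 1.24e-07), and 9 rose and 5 fell with fluvastatin, where the list was not called (adjusted p = 0.103). NF-kappaB cytokines and targets rose in 10 of 12 with lovastatin (median 2.28, adjusted p = 9.34e-06) and in 8 with simvastatin (1.58, adjusted p = 0.00225), led by TNFAIP3, CXCL3 and RELB, while with fluvastatin 4 rose and 4 fell (adjusted p = 0.75). NRF2 targets rose in 7 of 11 with lovastatin and with simvastatin (adjusted p = 0.00936 and 0.00351), and in 6 with fluvastatin without a call (adjusted p = 0.202). All the calls in these sentences held with an estimated correlation. Whether the statins differ is tested under the pairs of statins.

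Of the other lists at 20 µM in MiaPaCa-2, extracellular matrix and integrin genes rose in 7 of 13 with fluvastatin (adjusted p = 0.0441, but adjusted p = 0.0876 with an estimated correlation) and in 7 with lovastatin (adjusted p = 0.00363). Interferon-stimulated genes were called with lovastatin (adjusted p = 0.00363) and simvastatin (adjusted p = 0.0429, but adjusted p = 0.112 with an estimated correlation), with ISG15 at 1.78 and 2.93. ER chaperone and UPR genes rose in 9 of 14 with lovastatin (adjusted p = 0.00105), and BCL2 family genes in 6 of 11 with lovastatin (adjusted p = 0.0132), where PMAIP1 was at 2.76. SRF and actin cytoskeleton genes fell in 10 of 17 with simvastatin (adjusted p = 0.0454, but adjusted p = 0.174 with an estimated correlation), with VCL at -1.97. Cholesterol synthesis genes were again divided. MVD (mean 1.32), HMGCS1 (1.22) and LSS (1.17) rose with each statin, and ACAT2 fell from 46 ± 4.89 FPKM to 19.9 ± 1.61, 25.7 ± 2.85 and 28.4 ± 2.69 FPKM. The list had 8, 6 and 10 members up and 7, 3 and 4 down of 20 and was not called (adjusted p = 0.591, 0.63 and 0.11).

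At 20 µM 5579, 5028 and 5574 of 8534 genes were called with fluvastatin, lovastatin and simvastatin in MiaPaCa-2 (65.4%, 58.9% and 65.3%). The calls comprised 2806, 2462 and 2747 increases and 2773, 2566 and 2827 decreases, of which 1065, 966 and 1030 and 1097, 906 and 1091 were at least 2-fold. Against the same control as at 2 µM, the lovastatin contrast compared 2 with 2 libraries.

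The dose changed which genes moved in MiaPaCa-2, and the hypoxia genes raised at 2 µM were lower at 20 µM. All 13 hypoxia and glycolysis genes were lower at 20 than at 2 µM over the 3 statins, with a median of -1.99 (adjusted p = 5.33e-08). ANGPTL4 was back to 6.38 ± 1.59, 10.3 ± 2.03 and 6.74 ± 1.4 FPKM at 20 µM (log2 difference between doses -4.57, SE 0.09, adjusted p = 9.5e-17). Against the control at 20 µM, 4, 4 and 5 of the 13 were still higher with fluvastatin, lovastatin and simvastatin, among them NDRG1 (mean 3.22), HK2 (1.96) and VEGFA (1.89), and 6, 4 and 4 were lower, without a call of the list (adjusted p = 0.69, 0.713 and 0.596). ALDOC (-5.48), PPFIA4 (-4.64), the glucose transporter gene SLC2A3 (-4.53) and DOK3 (-4.36) were also lower. Higher at 20 than at 2 µM were KRT16 (5.71, SE 0.07, 5e-19), the cell junction gene HEG1 (4.05), TSC22D3 (3.84) and the complement inhibitor CD55 (3.5). All 20 mitosis genes and 21 of 23 replication genes were lower (adjusted p = 2.18e-10 and 1.33e-08). Higher lists were those of cell cycle inhibitors and p53 targets (10 of 12, adjusted p = 0.00047), the integrated stress response (13 of 18, 0.000783), Kruppel-like factors (7 of 8, 0.0086), NRF2 targets (9 of 11, 0.0131) and autophagy (9 of 13, 0.0107). NF-kappaB targets (7 of 12, adjusted p = 0.0371) and histones (6 of 8, adjusted p = 0.0261) were called with the preset correlation alone, with adjusted p = 0.0771 and 0.0734 with an estimated correlation. In total 6700 of 8534 genes differed between the doses, 3522 higher and 3178 lower at 20 µM, and 611 and 852 by at least 2-fold.

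In PANC-1 chemokine and other NF-kappaB target genes were higher at 2 µM than in the control. A few sterol synthesis genes were slightly higher, with a list call that was lost with an estimated correlation. All 3 statins were compared with the same control group. Whether the controls or cultures differed for another reason was not tested here. CXCL8, encoding the neutrophil chemokine interleukin 8, had 4.34 ± 4.95 FPKM (n = 3) in the control and 37.3 ± 0.88, 35 ± 4.34 and 31.6 ± 0.808 FPKM (n = 3 each) with fluvastatin, lovastatin and simvastatin at 2 µM. The chemokine gene CCL20 had 0.146 ± 0.246 FPKM in the control and 14.2 ± 2.83, 12.2 ± 0.457 and 11.7 ± 1.92 FPKM. SOD2, the mitochondrial superoxide dismutase, rose from 82.3 ± 6.2 to 353 ± 17.7, 312 ± 11.8 and 330 ± 21.4 FPKM. ACAT2, which makes acetoacetyl-CoA for sterol synthesis, rose from 42.6 ± 3.24 to 60.3 ± 3.18, 54.6 ± 3.76 and 60 ± 5.12 FPKM.

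The largest mean increases at 2 µM in PANC-1 were those of CCL20 (log2 fold change 3.59, SE 0.23, adjusted p = 5.8e-09), CXCL8 (3.15, SE 0.32, 3.9e-06), CXCL1 (3, SE 0.26, 7.2e-07), CXCL2 (2.57, SE 0.29, 1.4e-05) and IL32 (2.38, SE 0.15, 5.5e-09). FEZ1 (2.21), C15orf48 (2.19), PTX3 (2.11, SE 0.09, 2.2e-11), the complement gene C3 (2.08) and SOD2 (2, SE 0.07, 1.7e-12) followed. In control replicate 3, CXCL8 stood at 3.46 and CXCL1 at 4.57 on the log2 scale, against 1.67 and 0.87 for CXCL8 and 2.73 and 3.08 for CXCL1 in replicates 1 and 2. Fits of 2 groups alone lost the calls of CXCL8 for all 3 statins, of CXCL1 for simvastatin, of FEZ1 for lovastatin and of C3 for all 3. The call of C3 for fluvastatin was also lost with a pseudocount of 0.1 (2.94), without control 1 (1.37) or without fluvastatin replicate 1 (1.46) or 2 (1.81). Among the largest decreases were those of the mitochondrial pseudogenes MTATP6P1 (-1.56, SE 0.14, 8e-07) and MTND2P28 (-1.14). MAT2A, which makes the methyl donor S-adenosylmethionine, had -0.86 (SE 0.08, 1.2e-06). EMP1, also among the largest decreases (-0.9), was no longer called for fluvastatin (-0.52) and simvastatin (-0.54) without control replicate 3. Its call was also lost for fluvastatin without fluvastatin replicate 1 (-0.78), 2 (-0.85) or 3 (-0.73), for simvastatin without simvastatin replicate 1 (-0.71) or 3 (-0.8), and for all 3 in fits of 2 groups alone, where MAT2A lost its calls for fluvastatin (-0.82) and lovastatin (-0.77).

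NF-kappaB cytokines and targets rose in 9 of 13 with each statin at 2 µM in PANC-1, with medians of 1.48, 1.42 and 1.40 (camera adjusted p = 2.44e-17, 3.35e-19 and 5.78e-16), and 10, 9 and 9 rose when adjusted over the list alone. That call held with an estimated correlation (adjusted p = 5.51e-06, 2.92e-06 and 9.15e-06). Cholesterol synthesis genes rose in 6, 3 and 6 of 20, including ACAT2 (mean 0.44), MSMO1 (0.44) and DHCR7 (0.42), with adjusted p = 3.18e-05, 0.000181 and 5.51e-05. Adjusted over the list alone 8, 6 and 8 rose, and the list's adjusted p = 0.0558, 0.108 and 0.0866 with an estimated correlation. Hypoxia and glycolysis genes rose in 5, 1 and 5 of 14, led by BNIP3, a mitophagy gene (1.74), with adjusted p = 2.66e-08, 0.000219 and 1.1e-05. With an estimated correlation this held for fluvastatin (adjusted p = 0.0471) and was lost for lovastatin and simvastatin (adjusted p = 0.193 and 0.113). Control replicate 3 had PFKFB4 at 4.22 and NDRG1 at 6.22, against 1.96 and 2.1 for PFKFB4 and 5.06 and 4.82 for NDRG1 in replicates 1 and 2. Without that library and simvastatin 20 µM replicate 3, 10, 8 and 8 hypoxia genes rose (adjusted p = 4.01e-17, 1.56e-12 and 3.54e-13), and the call held with an estimated correlation (adjusted p = 1.13e-05, 5.76e-05 and 4.42e-05).

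Interferon-stimulated genes rose in 2, 2 and 1 of 9 at 2 µM in PANC-1, with IFI6 at 0.92 (adjusted p = 0.00315, 0.00658 and 0.0111). With an estimated correlation the call held for fluvastatin (adjusted p = 0.0471) and not for lovastatin and simvastatin (adjusted p = 0.0824 and 0.0866 with an estimated correlation). Fatty acid synthesis, with FADS2 at 0.54, and Kruppel-like factors, with KLF4 at 0.59, were called for fluvastatin (adjusted p = 0.0332 and 0.0188, but adjusted p = 0.094 and 0.095 with an estimated correlation). Mesenchymal markers were called higher for fluvastatin as a list (adjusted p = 0.0332, but adjusted p = 0.184 with an estimated correlation), although none of the 12 rose. With lovastatin, reference genes were called higher (adjusted p = 0.00756), with TFRC at 1.16, and cytosolic ribosomal protein genes lower (adjusted p = 0.0411), with RPL13 at -0.37, but adjusted p = 0.172 and 0.562 with an estimated correlation. No mitosis or replication list was called at this dose. Without the 2 libraries that stood apart, and with an estimated correlation, the interferon (adjusted p = 0.0078, 0.00892 and 0.0194) and Kruppel-like lists (adjusted p = 0.0146, 0.0429 and 0.0459) were called with each statin, the cholesterol list with fluvastatin and simvastatin (adjusted p = 0.0298 and 0.0459), and reference genes with lovastatin and simvastatin (adjusted p = 0.00856 and 0.0312). The preset calls of fatty acid synthesis and mesenchymal markers with fluvastatin (adjusted p = 0.083 and 0.164) and of ribosomal protein genes with lovastatin (adjusted p = 0.951) were lost there.

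Of 8615 genes tested, 340, 242 and 342 were called with fluvastatin, lovastatin and simvastatin at 2 µM in PANC-1 (3.95%, 2.81% and 3.97%). Increases numbered 255, 170 and 232 and decreases 85, 72 and 110, with 47, 37 and 40 increases and 11, 6 and 14 decreases of at least 2-fold. Without the 2 libraries that stood apart, the counts were 464, 378 and 561, and fits of 2 groups alone called 58, 47 and 30. Leaving out 1 library moved the count by over 1.5 times for fluvastatin (189 without fluvastatin replicate 3), lovastatin (125 without lovastatin replicate 3) and simvastatin (226 without simvastatin replicate 1).

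At 20 µM PANC-1 cells raised nearly the whole pathway of cholesterol synthesis and lowered the genes of cell division. HMGCS1, an early enzyme of sterol synthesis, rose from 25.9 ± 3.05 FPKM to 241 ± 12.9, 205 ± 1.57 and 179 ± 6.21 FPKM (n = 3 each) with fluvastatin, lovastatin and simvastatin. ACAT2 rose to 295 ± 7.79, 319 ± 5.58 and 328 ± 11.5 FPKM. CCNB1 fell from 334 ± 7.62 to 23.7 ± 1.17, 48.2 ± 2.05 and 54.8 ± 8.54 FPKM, and the mitotic kinase gene PLK1 from 93.2 ± 7.73 to 6.85 ± 2.19, 21.9 ± 8.21 and 11.9 ± 2.95 FPKM.

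Among the largest mean increases at 20 µM in PANC-1 were those of S100P (log2 fold change 5.28, SE 0.36, adjusted p = 5.8e-10), TSC22D3 (4.65, SE 0.09, 3.4e-17), ATF3 (4.39, SE 0.15, 2.6e-14) and the transcription factor KLF2 (3.96, SE 0.35, 2e-08). BEX2 (3.67), RAB39B (3.58), the acetyl-CoA synthetase ACSS2 (3.53), LAMP3 (3.37) and BEX4 (3.19) followed. The largest decreases were those of PBK (-3.16, SE 0.12, 1.1e-13), CCNB1 (-3.04, SE 0.07, 3.3e-16), DLGAP5 and TROAP (-2.96 each), and the securin gene PTTG1 (-2.94). CDCA3, NUF2, PLK1, KIF20A and RRM2 had values between -2.94 and -2.82.

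Cholesterol synthesis genes rose in 19, 19 and 20 of 20 at 20 µM in PANC-1, with medians of 2.00, 1.89 and 1.92 (camera adjusted p = 1.63e-12, 2.25e-18 and 3.2e-15). Sterol uptake and SREBP regulation genes rose in 8, 7 and 9 of 11, among them STARD4 (mean 2.67) and INSIG1 (2.08), with adjusted p = 0.00386, 0.00193 and 0.00759, and fatty acid synthesis genes in 9, 8 and 6 of 10, among them ME1 (2.06) and SCD (1.28), with adjusted p = 0.000135, 6.59e-06 and 0.0142. All 20 mitosis genes fell, with medians of -3.47, -1.93 and -2.25 (adjusted p = 2.59e-16, 2.25e-18 and 3.2e-15), and 23, 21 and 22 of 23 replication genes fell (adjusted p = 1.12e-14, 1.21e-10 and 4.79e-10). Integrated stress response genes rose in 17, 15 and 16 of 18, including DDIT3 (2.47) and SESN2 (2.46), with adjusted p = 1.1e-10, 1.21e-10 and 4.79e-10. NRF2 targets rose in 8, 8 and 7 of 10, including the heme oxygenase gene HMOX1 (3.13) and GCLC (2.42), with adjusted p = 0.00011, 3.07e-05 and 3.43e-05. Kruppel-like factors rose in 7, 7 and 6 of 8 (adjusted p = 0.000591, 0.00108 and 0.00759) and autophagy genes in 9, 8 and 8 of 13 (adjusted p = 0.00441, 0.00709 and 0.0268). All of these calls held with an estimated correlation.

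Other lists at 20 µM in PANC-1 were called less firmly or with some statins. Cell cycle inhibitors and p53 targets rose in 9, 5 and 7 of 12, led by BBC3 (2.19), with adjusted p = 0.00656, 0.0385 and 0.0124, and the call with lovastatin had adjusted p = 0.0943 with an estimated correlation. YAP and TAZ targets fell in 11 of 16 with fluvastatin and in 10 with simvastatin (adjusted p = 0.000226 and 0.01, but adjusted p = 0.0723 and 0.181 with an estimated correlation) and were not called with lovastatin (adjusted p = 0.86). Epithelial markers rose in 9, 7 and 7 of 12, with the claudin genes CLDN3 and CLDN7 at 1.87 and CLDN4 at 1.83 (adjusted p = 0.00441, 0.00785 and 0.0162, but adjusted p = 0.0977, 0.127 and 0.174 with an estimated correlation). Histone mRNAs, read here in poly-A selected libraries, rose in 6, 5 and 6 of 7 (adjusted p = 0.0295, 0.0365 and 0.0116), and the calls with fluvastatin and lovastatin had adjusted p = 0.0761 and 0.0951 with an estimated correlation. SRF and actin cytoskeleton genes fell in 11 of 17 with fluvastatin (adjusted p = 0.00762, but adjusted p = 0.0648 with an estimated correlation), with ACTB at -1.91, and rose in 9 with lovastatin (adjusted p = 0.0385, but adjusted p = 0.125 with an estimated correlation), with CNN1 at 2.7. MAPK feedback and immediate early genes fell in 10 of 14 with fluvastatin and rose in 5 with lovastatin (adjusted p = 0.0152 and 0.02, but adjusted p = 0.0872 and 0.107 with an estimated correlation), with ETV4 at -2.23 and DUSP5 at 1.79. The NF-kappaB list fell in 6 of 13 with fluvastatin (adjusted p = 0.0357, but adjusted p = 0.0675 with an estimated correlation), with CXCL1 at -3.09, and ER chaperone and UPR genes rose in 8 of 14 with lovastatin (adjusted p = 0.00709), with HSPA5 at 1.6. Mesenchymal markers fell in 8 of 12 and cytosolic ribosomal protein genes rose in 8 of 14 with simvastatin (adjusted p = 0.0371 each, but adjusted p = 0.172 and 0.429 with an estimated correlation), with CD44 at -1.09 and RPL10 at 1.

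The genes called at 20 µM in PANC-1 numbered 5466, 3993 and 5130 of 8615 with fluvastatin, lovastatin and simvastatin (63.4%, 46.3% and 59.5%). They comprised 2798, 2063 and 2532 increases and 2668, 1930 and 2598 decreases, of which 928, 445 and 696 and 902, 351 and 663 were at least 2-fold. Without the 2 libraries that stood apart, the lists lost with the preset correlation included SRF and actin genes with lovastatin (adjusted p = 0.111) and NF-kappaB targets with fluvastatin (adjusted p = 0.0709). In that fit the estimated correlation also called YAP and TAZ targets with fluvastatin and simvastatin (adjusted p = 0.00338 and 0.0139), SRF and actin genes and epithelial markers with fluvastatin (adjusted p = 0.0193 and 0.0268), p53 targets with lovastatin (adjusted p = 0.0446) and ribosomal protein genes with simvastatin (adjusted p = 0.0132). It no longer called autophagy genes and histones with simvastatin (adjusted p = 0.0661 and 0.0676 with an estimated correlation).

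**Figure D2:**
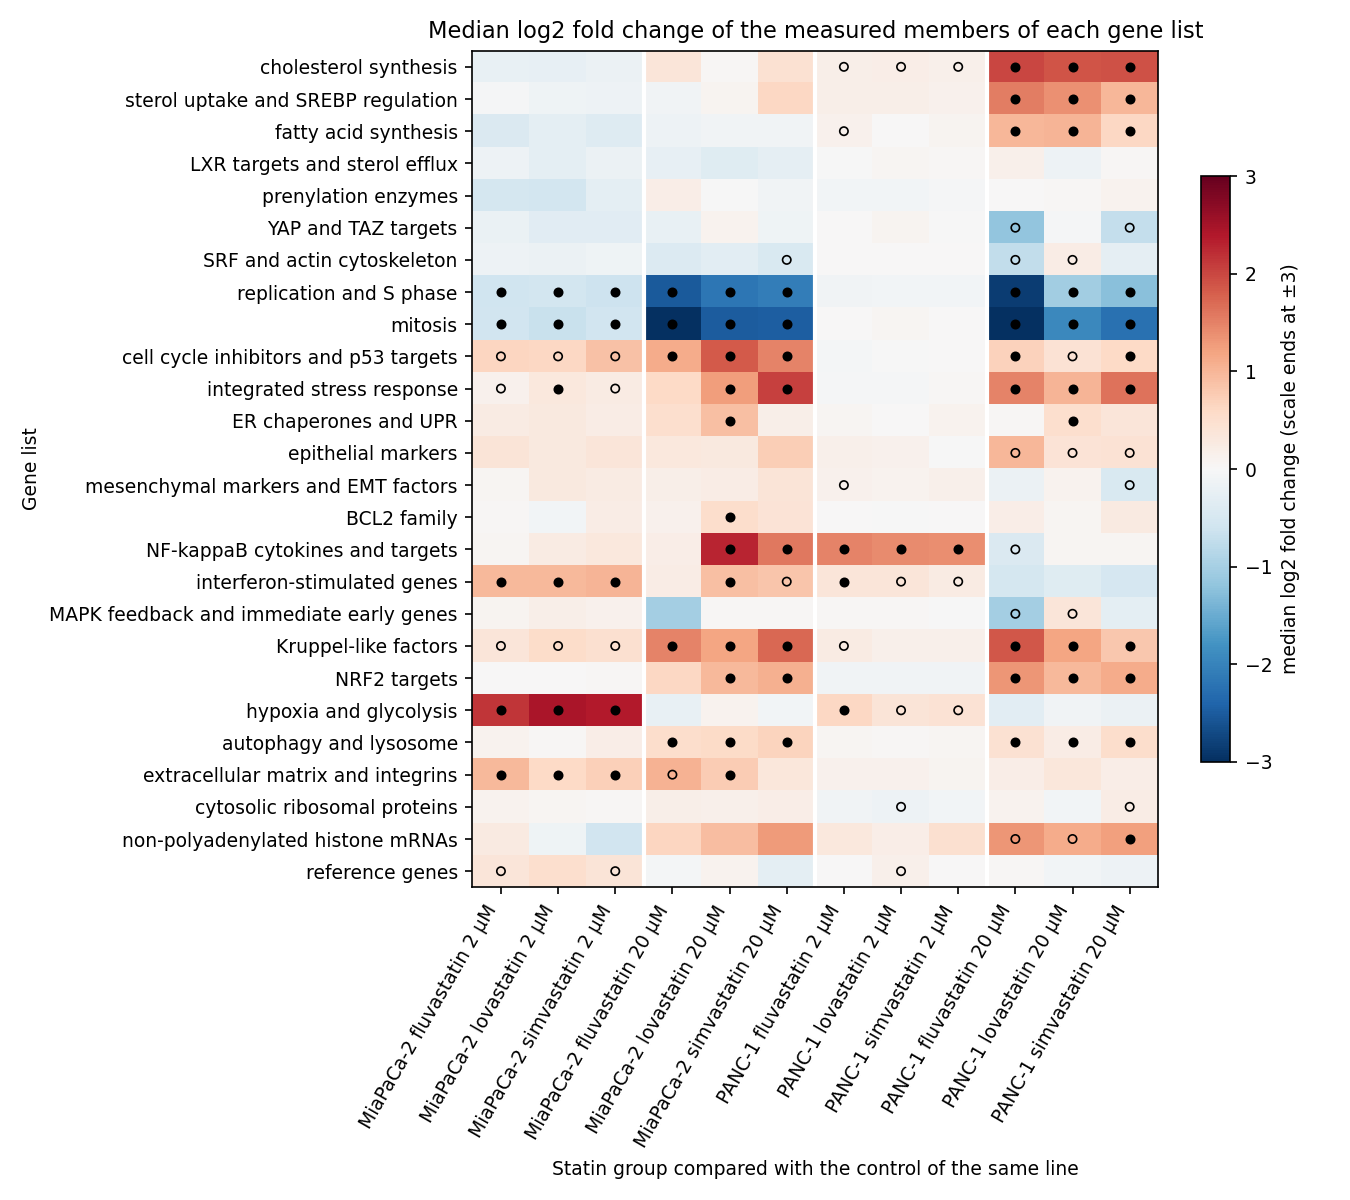
Median log2 fold change (colour) of the measured members of each gene list shown (vertical axis) in each statin group against the control of its line (horizontal axis); filled dots mark lists with an adjusted p under 0.05 with preset and with estimated correlation, and open dots mark lists called with the preset correlation alone. Cholesterol synthesis has medians of 2.00, 1.89 and 1.92 in PANC-1 at 20 µM, and hypoxia and glycolysis has 2.13, 2.45 and 2.38 in MiaPaCa-2 at 2 µM.

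The dose also divided the PANC-1 response. The chemokine genes that were higher than the control at 2 µM were lower at 20 than at 2 µM. Of 13 NF-kappaB genes, 11 were lower at 20 than at 2 µM (median -1.92, adjusted p = 0.000155), with CXCL1 at -4.81 (SE 0.18, 7.4e-14) and CCL20 at -3.28 (SE 0.16, 2.5e-12). CXCL8 stood at 2.79 ± 0.431, 4.13 ± 0.368 and 3.79 ± 1.16 FPKM at 20 µM and passed no test against the control (-0.09, 0.36 and 0.23). Without control replicate 3 it was called higher than the control with each statin at 20 µM (0.64, 1.08 and 0.96, adjusted p = 0.011, 0.00039 and 0.00075). Also lower were the proliferation marker MKI67 (-3.29), ARHGEF39 (-3.11) and PBK (-2.99), with all 20 mitosis and all 23 replication genes (adjusted p = 8.91e-14 and 2.36e-11). S100P (4.85), TSC22D3 (4.38), ATF3 (3.82), BEX2 (3.65) and KLF2 (3.64) were higher at 20 µM. Cholesterol synthesis genes were higher in 19 of 20 (adjusted p = 2.55e-12), integrated stress response genes in 16 of 18 (2.44e-09), NRF2 targets in 8 of 10 (2.74e-05), fatty acid synthesis genes in 8 of 10 (0.00118), Kruppel-like factors in 7 of 8 (0.00354), cell cycle inhibitors and p53 targets in 7 of 12 (0.00986) and autophagy genes in 9 of 13 (0.0169). Those lists held with an estimated correlation. Called with the preset correlation alone were sterol uptake, epithelial, ribosomal protein and histone genes, which were higher, and YAP and TAZ targets, interferon-stimulated and hypoxia genes, which were lower. Without the 2 libraries that stood apart, all of these but sterol uptake and histone genes were also called with an estimated correlation (adjusted p between 0.0136 and 0.036). In total 6385 of 8615 genes differed between the doses, 3172 higher and 3213 lower at 20 µM, and 568 and 565 by at least 2-fold.

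The statins were compared with each other at matched dose to ask whether their responses differed. How strongly each statin inhibited mevalonate synthesis is not given in the sources used here. A difference between statins therefore cannot be assigned to structure rather than to unequal inhibition at the same dose. At 2 µM the 95% interval of the difference lay within 2-fold for 95.3%, 95.1% and 95.1% of genes in MiaPaCa-2 and for 94.7%, 95.1% and 94.4% in PANC-1, for simvastatin against lovastatin, fluvastatin against lovastatin and fluvastatin against simvastatin. With limma, MiaPaCa-2 at 2 µM had 25, 0 and 48 genes called and 843, 828 and 1080 at an unadjusted p under 0.05, and PANC-1 had 0, 1 and 1 called and 365, 497 and 541 at an unadjusted p under 0.05. In MiaPaCa-2 the largest differences included SIPA1L3, higher with simvastatin than with lovastatin (2.24, SE 0.36, adjusted p = 0.0091), and LMO4, higher with fluvastatin than with simvastatin (1.1, SE 0.18, 0.019). In PANC-1 the genes called were the pseudogene RPL35AP21, lower with fluvastatin than with lovastatin (-1, 0.002), and CCNL2, higher with fluvastatin than with simvastatin (0.48, 0.027). No list call at 2 µM held with an estimated correlation. LMO4 lost its call when any of 5 libraries was left out (0.9 to 1.13), SIPA1L3 without simvastatin 2 µM replicate 2 (2.08), and CCNL2 when any of 5 was left out (0.45 to 0.5), and LMO4 and CCNL2 also lost theirs in fits of 2 groups alone. Simvastatin against lovastatin in MiaPaCa-2 had 2 genes in a fit of 2 groups alone. With 1 library left out, it fell to 15 at the lowest, fluvastatin against lovastatin reached 39 without fluvastatin 2 µM replicate 1, and fluvastatin against simvastatin ran from 4 without fluvastatin 2 µM replicate 3 to 71 without fluvastatin 2 µM replicate 1.

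At 20 µM in MiaPaCa-2 the statins gave different levels of many genes, among them inflammatory and stress genes and a keratin. CXCL8 had 42 ± 2.49 FPKM in the control and 26.7 ± 2.22, 425 ± 4.82 and 152 ± 14.3 FPKM with fluvastatin, lovastatin and simvastatin (fluvastatin less lovastatin -3.95, SE 0.1, adjusted p = 5.7e-13). HMOX1 had 15.2 ± 0.668 in the control and 32 ± 4.55, 53 ± 1.02 and 348 ± 4.24 FPKM (simvastatin less lovastatin 2.69, SE 0.11, 6e-11). KRT15, a basal keratin, had 1210 ± 39.1, 808 ± 4.15 and 123 ± 12.9 FPKM, against 65.9 ± 0.651 in the control (simvastatin less lovastatin -2.71, SE 0.07, 2.4e-13). HMGCS1 was lower with fluvastatin than with simvastatin by a log2 difference of -1.25 (95% interval -1.49 to -1, adjusted p = 1.6e-07).

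Fluvastatin gave lower values than lovastatin at 20 µM in MiaPaCa-2 for CSF3, a granulocyte growth factor (-3.85, SE 0.16, 6.7e-11), the AP-1 factor FOSL1 (-3.29), the urokinase receptor PLAUR (-3.15) and PTX3 (-2.98), and higher values for KLK7 (1.82) and CLIC3 (1.72). Of 12 NF-kappaB genes 10 were lower with fluvastatin than with lovastatin (median -2.39, adjusted p = 4.83e-13), as were 13 of 14 MAPK feedback and immediate early genes (-1.59, 4.9e-13), 17 of 18 integrated stress response genes (-0.87, 4.81e-17) and 17 of 20 mitosis genes (2.31e-11). Against simvastatin, fluvastatin gave lower values in all 18 integrated stress response genes (median -1.67, adjusted p = 1.36e-14), 10 of 12 NF-kappaB genes (2.72e-05) and 11 of 14 MAPK genes (1.23e-05), with UPP1 at -3.39 and VGF at -3.14, and higher values for PTGDS (4.48), KRT15 (3.29) and KLK5 (3.27). Simvastatin exceeded lovastatin in 17 of 18 integrated stress response genes (median 0.75, adjusted p = 3.46e-12), and all these list calls held with an estimated correlation. NF-kappaB genes were lower with simvastatin than with lovastatin in 7 of 12 (adjusted p = 0.0268, but adjusted p = 0.104 with an estimated correlation). NRF2 targets were lower with fluvastatin than with lovastatin in 6 of 11 (adjusted p = 0.000286) and than with simvastatin in 9 of 11 (adjusted p = 0.00123), and both calls held with an estimated correlation. For simvastatin against lovastatin 5 were higher and 1 lower (adjusted p = 0.0459, but adjusted p = 0.117 with an estimated correlation). Replication, hypoxia, interferon, ER chaperone, and YAP and TAZ genes were also lower as lists with fluvastatin than with lovastatin, and mitosis, replication and hypoxia genes were lower than with simvastatin, with both correlations. Some other lists were called with the preset correlation alone. In total 3184, 2009 and 4795 genes differed for simvastatin against lovastatin, fluvastatin against lovastatin and fluvastatin against simvastatin, and the 95% interval lay within 2-fold for 77.2%, 82.8% and 70.1% of genes. For fluvastatin against lovastatin the count was 1170 without lovastatin 20 µM replicate 2 and 1173 in a fit of the 2 groups alone.

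In PANC-1 at 20 µM fluvastatin gave lower levels of most cell division genes, and higher levels of most integrated stress response genes, than the other statins. RRM2 had 10.9 ± 2.57, 99.2 ± 1.69 and 51.1 ± 10.6 FPKM with fluvastatin, lovastatin and simvastatin, against 277 ± 11.2 in the control (fluvastatin less lovastatin -3.09, SE 0.13, adjusted p = 6.6e-12). CTGF, a matrix protein and YAP target, had 27.2 ± 0.467, 191 ± 5.74 and 114 ± 4.88 FPKM, against 94.8 ± 13.4 in the control (-2.76, SE 0.08, 2.6e-14). The ectonucleotidase gene NT5E had 30.8 ± 2.77, 257 ± 11.3 and 113 ± 3.66 FPKM, against 166 ± 11.3 (-3.03, SE 0.07, 5.1e-16), and the small heat shock protein gene HSPB1 had 1610 ± 99.8, 496 ± 12.6 and 993 ± 37.9 FPKM, against 194 ± 21.4 (1.7, SE 0.07, 3.3e-12).

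Compared with lovastatin, fluvastatin gave lower values at 20 µM in PANC-1 for 20 of 23 replication genes (median -1.73, adjusted p = 1.49e-19), 19 of 20 mitosis genes (-1.51, 4.31e-19), 14 of 17 SRF and actin genes (7.42e-10), 11 of 16 YAP and TAZ targets (1.34e-09) and 11 of 14 MAPK genes (5.26e-09), and higher values for 16 of 18 integrated stress response genes (7.52e-11). FAM111B (-3.27) and CCL2 (-2.74) were among the lower genes and BMF, which promotes cell death (1.77), among the higher. Fluvastatin was also below simvastatin in 19 of 23 replication and 19 of 20 mitosis genes (adjusted p = 2.67e-12 and 8.09e-12) and above it in 13 of 18 integrated stress response genes (0.00691). Simvastatin exceeded lovastatin in 10 of 18 integrated stress response genes (adjusted p = 0.000695) and was lower in 10 of 17 SRF and actin genes (0.000364), with the integrin gene ITGA2 at -1.6 (SE 0.1, 5.8e-09). These list calls held with an estimated correlation. Simvastatin was also below lovastatin in 12 of 16 YAP and TAZ targets and 7 of 12 mesenchymal markers (adjusted p = 5.21e-05 and 0.000392, but adjusted p = 0.0724 and 0.0546 with an estimated correlation). NF-kappaB genes were lower and NRF2 targets, p53 targets, autophagy and Kruppel-like genes higher as lists with fluvastatin than with lovastatin, and MAPK genes were lower and fatty acid synthesis, autophagy and Kruppel-like genes higher than with simvastatin, with both correlations. Further lists were called with the preset correlation alone. In total 3319, 2645 and 4096 genes differed for simvastatin against lovastatin, fluvastatin against lovastatin and fluvastatin against simvastatin, with 82.2%, 81.5% and 75.6% of intervals within 2-fold. In simvastatin replicate 3, PTP4A1 stood at 6.49 on the log2 scale against 9.01 and 9.09 in replicates 1 and 2, and ANG, called higher with simvastatin (2.21), was no longer called without that library (1.59), without lovastatin replicate 1 (2) or 3 (1.78), or in a fit of 2 groups alone, where PTP4A1 also lost its call (-1.94).

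The lines were compared to ask whether they responded alike. At 20 µM cell division genes fell and ATF3 and Kruppel-like factors rose in each line, and sterol synthesis responded differently. In a test of the difference itself, averaged over the statins, 18 of 20 cholesterol synthesis genes responded higher in PANC-1 (camera adjusted p = 4.22e-17), as did 9 of 10 fatty acid synthesis genes (1.06e-07) and 12 of 23 replication genes (0.00215), which fell less there. Responses higher in MiaPaCa-2 were those of 7 of 12 cell cycle inhibitors and p53 targets (adjusted p = 8.22e-06), 10 of 14 NF-kappaB genes (8.39e-06), 8 of 9 interferon-stimulated genes (2.18e-05) and 6 of 14 extracellular matrix genes (0.0181). These calls held with an estimated correlation, while those of YAP and TAZ targets, mesenchymal markers and NRF2 targets (adjusted p = 0.0142, 0.00822 and 0.0273) did not (adjusted p = 0.0848, 0.0545 and 0.121 with an estimated correlation), except without the 2 PANC-1 libraries that stood apart (adjusted p = 0.00767, 0.0182 and 0.0182). The mitosis and Kruppel-like lists passed no test of the difference (adjusted p = 0.171 and 0.359), which does not show that they responded alike. ACAT2 rose by 2.85 log2 units in PANC-1 and was at -0.89 in MiaPaCa-2 (difference 3.74, adjusted p = 3.5e-20), the sterol transport gene STARD4 was at 2.67 and -0.2 (2.87), and TMEM97 at 1.5 and -1.13 (2.63, 4.1e-15). HMGCS1 was at 2.95 and 1.22 (difference 1.73, 1.6e-12) and SQLE at 2.29 and 0.56 (1.73, 8.3e-08). KRT16 rose more in MiaPaCa-2 (1.45 and 6.47, difference -5.01, 1.1e-22), as did CDKN1A (1.19 and 3.73, -2.54, 1.9e-17), and the metastasis suppressor gene CD82 was at -1.88 and 2.65 (-4.53). KLF2 rose more in PANC-1 (3.96 and 2.61, difference 1.34, 0.012), and ATF3 was at 4.39 and 4.57 (difference -0.18, adjusted p = 0.54).

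At 2 µM the fold changes of the lines were hardly correlated across genes, while the hypoxia and interferon lists were called higher in both lines with each statin with the preset correlation. In PANC-1 those calls were lost with lovastatin and simvastatin for hypoxia (adjusted p = 0.193 and 0.113 with an estimated correlation) and interferon genes (adjusted p = 0.0824 and 0.0866 with an estimated correlation). The hypoxia response was higher in MiaPaCa-2 in 11 of 14 genes (adjusted p = 4.76e-08), as was the integrated stress response in 10 of 18 (0.00292), while 8 of 14 NF-kappaB, 12 of 20 mitosis and 13 of 23 replication genes responded higher in PANC-1 (0.00348, 0.000149 and 0.00954), all also with an estimated correlation. Each difference at 2 µM includes the MiaPaCa-2 change from a control of 2 libraries. In that change, differing controls or culture conditions cannot be told apart from a statin effect. Cholesterol synthesis, and cell cycle inhibitors and p53 targets, differed with the preset correlation alone (adjusted p = 0.0229 and 0.0192, but adjusted p = 0.147 and 0.0713 with an estimated correlation). Without the 2 PANC-1 libraries that stood apart, extracellular matrix genes (adjusted p = 0.0173, and 0.0466 with an estimated correlation) and interferon genes (adjusted p = 0.0392, but adjusted p = 0.0622 with an estimated correlation) were also called higher in MiaPaCa-2. CXCL1 was at 3 in PANC-1 and -0.31 in MiaPaCa-2 (difference 3.3, adjusted p = 1.6e-09), and CXCL8 at 3.15 and 0.22 (2.92, 4.8e-07). MUC1 was at -0.83 and 4.62 (-5.45, 3.6e-09) and TXNIP, which limits glucose uptake, at -1.53 and 2.9 (-4.43). In PANC-1 control replicate 3 MUC1 stood at 8.09 and TXNIP at 6.24, against 5.45 and 5.91 for MUC1 and 2.96 and 3.53 for TXNIP in replicates 1 and 2. Over 8411 genes tested in both lines, the mean responses correlated across genes with a Pearson r of 0.00626 at 2 µM and 0.713 at 20 µM (Spearman -0.0123 and 0.685); genes are not independent replicates, and no p is given. Without the 2 PANC-1 libraries that stood apart, the correlation at 2 µM was 0.221 (Spearman 0.156). At 20 µM 1628 genes rose in both lines and 1851 fell in both, where 882 and 872 would be shared if the lines were independent, and 328 moved in opposite directions. At 2 µM 127 rose and 41 fell in both, where 82 and 46 would be shared, and 119 moved in opposite directions. Responses differed between the lines for 2597, 2952 and 2847 genes at 2 µM and 2991, 2837 and 4026 at 20 µM, for fluvastatin, lovastatin and simvastatin.

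**Figure D3:**
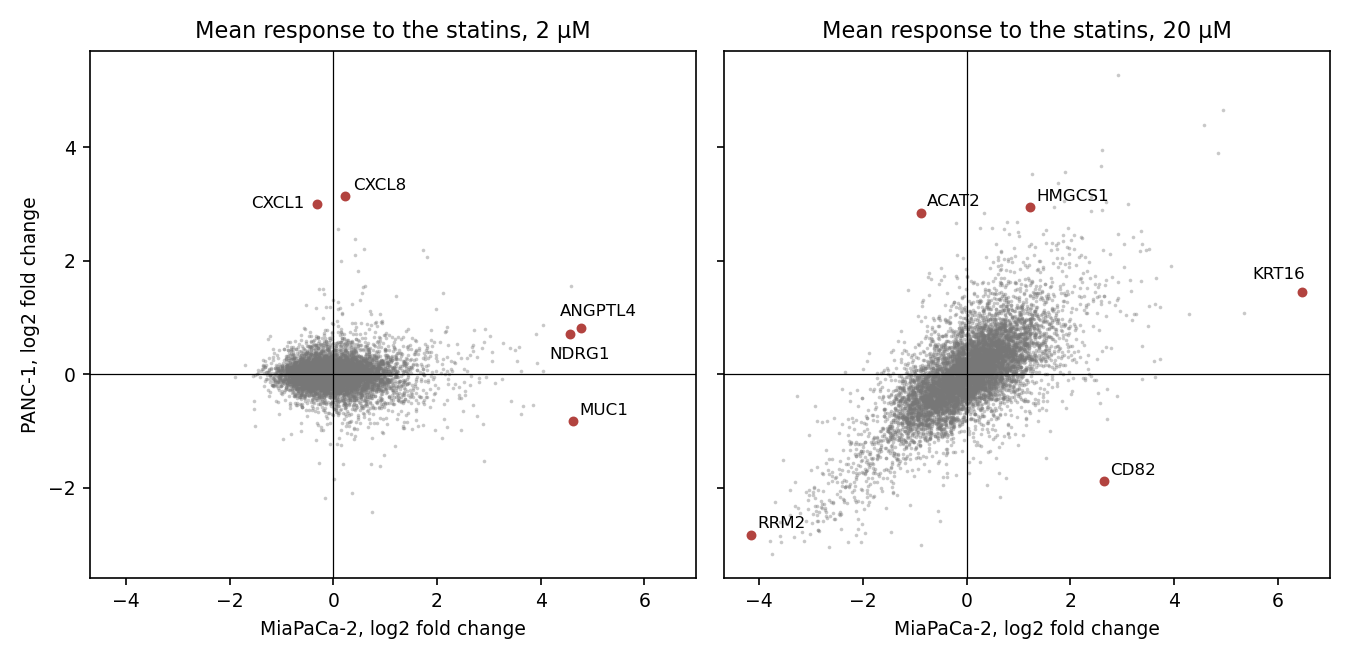
Mean log2 fold change over the 3 statins in MiaPaCa-2 (horizontal axis) and PANC-1 (vertical axis) for each gene tested in both lines, at 2 µM (left) and 20 µM (right); named genes are red. The values correlate across genes with a Pearson r of 0.00626 at 2 µM and 0.713 at 20 µM. Without PANC-1 control replicate 3 and simvastatin 20 µM replicate 3, the r is 0.221 at 2 µM and 0.713 at 20 µM.

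The statins of a line changed many genes in the same direction, and some in opposite directions at 20 µM. All 3 statins called the same direction for 2860 genes at 2 µM and 3393 at 20 µM in MiaPaCa-2, and for 143 and 2689 in PANC-1. Those called with any statin numbered 4837 and 7235 in MiaPaCa-2 and 525 and 7020 in PANC-1, and statins called opposite directions for 1 and 370 of them in MiaPaCa-2 and for 0 and 336 in PANC-1. In MiaPaCa-2 at 2 µM 1437 genes rose with all 3, including the NDRG1, ANGPTL4 and MUC1 genes, and 1423 fell. In PANC-1 at 2 µM 115 rose, including CCL20, CXCL1 and SOD2, and 28 fell; without the 2 libraries that stood apart 249 genes were called the same way. Statins compared with the same control share its error. In 20 simulations no gene changed, and every group of a line, control included, was drawn with noise independent between genes. The highest such count in them was 0. Few calls can arise in such data, so this count cannot show what controls that deviate in many genes would give. The mean covariance of the fold changes of 2 statins less the simulated covariance was 0.341 and 0.736 in MiaPaCa-2 and 0.0461 and 0.475 in PANC-1 at 2 and 20 µM. The controls were too few to be divided between the statins, so part of that excess may come from the shared controls.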

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

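The tests of the oxygen or density of the cultures in MiaPaCa-2, of the growth of the response with the dose in genes chosen on other libraries and in gene lists, and of the PANC-1 libraries that stood apart were chosen after the result was seen. Each result in the next 2 paragraphs drew attention because the lines responded differently in a test of the difference itself, the interaction of line and statin. Differences are PANC-1 less MiaPaCa-2 on the log2 scale.

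At 2 µM the responses differed for 2597, 2952 and 2847 genes with fluvastatin, lovastatin and simvastatin. Averaged over the statins, the chemokine genes CCL20 (3.41), CXCL1 (3.3), CXCL8 (2.92), CXCL2 (2.47) and CCL2 (2.12) responded higher in PANC-1. The membrane mucin gene MUC1 (-5.45), TXNIP (-4.43), PTGDS (-4.38), DOK3 (-4.32) and the noncoding FER1L4 (-4.22) responded higher in MiaPaCa-2. CCL20 and CCL2 were below the expression filter in MiaPaCa-2. Without PANC-1 control replicate 3 the differences were 3.65 for CXCL8, -4.65 for MUC1, -3.43 for TXNIP and for PTGDS, -3.14 for DOK3 and -3.6 for FER1L4, and all were still called. These differences also rest on the MiaPaCa-2 control of 2 libraries. In MiaPaCa-2 at 2 µM, differing controls or culture conditions cannot be told apart from a statin effect.

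At 20 µM the responses differed for 2991, 2837 and 4026 genes. The sterol genes ACAT2 (3.74), STARD4 (2.87) and TMEM97 (2.63) responded higher in PANC-1, as did BEX4 (3.07) and the neuropeptide gene NMU (2.89). KRT16 (-5.01), CD82 (-4.53), PTGDS (-4.26), the calcium-binding protein gene S100A2 (-3.68) and the NF-kappaB inhibitor TNFAIP3 (-3.5) responded higher in MiaPaCa-2. BEX4 was below the expression filter in MiaPaCa-2. Without PANC-1 control replicate 3 the difference for PTGDS was -3.31, and without control replicate 1 it was -4.84.

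In MiaPaCa-2 the libraries at 2 µM stood far from the control, with hypoxia genes in front. A response that grows with the dose was argued against as the whole of the pattern, since at most 49.6% of the genes called the same way with 2 statins moved further from 2 to 20 µM of the third, where over 60% were predicted, and all 13 hypoxia and glycolysis genes were lower at 20 than at 2 µM. It may hold for mitosis and replication genes, 41 of which were lower at 20 than at 2 µM (20 of 20 and 21 of 23), and a response like that of PANC-1 at 20 µM may be part of the pattern, with a Pearson r of 0.35 across the genes called the same way with all 3 statins, which are not independent replicates. Controls that differed from all treated libraries for another reason cannot be told apart from a statin effect, because the line has 1 control group of 2 libraries and the share of those genes that moved further (40.6%) rests on the same 2 µM libraries as their choice, while at 20 µM ANGPTL4 was back near the control but NDRG1 was 3.22 above it. Lower oxygen or denser cultures at 2 µM cannot be told apart from a statin effect either, since all 13 hypoxia and glycolysis genes rose with each statin and no label gives oxygen or density.

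In PANC-1 control replicate 3 stood apart from replicates 1 and 2, with 80 genes at least 2 log2 units above both; UCA1, for example, had 3460 FPKM against 0.00348 and 0.00334. A statin-treated PANC-1 library under the control's name was argued against, since the deviation had an r of 0.647 across genes with the difference between the lines, larger by 0.315 than the larger r with the statin responses (0.332 and 0.129). RNA or cells of the MiaPaCa-2 line may be in the library, but this stays open, since 40 of 45 genes high in MiaPaCa-2 and nearly absent from PANC-1 (88.9%) lay above every other PANC-1 library, short of the 90% set for the test. Those genes were at a median of 19.6% of their MiaPaCa-2 level (quartiles 16.6 and 29.3%), and genes of PANC-1 alone at 79% of their PANC-1 level, as a lower share of PANC-1 RNA predicts, although the latter value was also low in PANC-1 libraries with fluvastatin at 20 µM. No biological explanation was tested.

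In PANC-1 simvastatin 20 µM replicate 3 also stood apart, with 13 genes at least 2 log2 units below replicates 1 and 2 and 7 above them, although MiaPaCa-2 fluvastatin 2 µM replicate 1, which was not weighed, also had 13 below and 0 above. A large share of MiaPaCa-2 RNA or cells was argued against, since MiaPaCa-2 genes were at a median of 1.69% of their MiaPaCa-2 level. A small share was not excluded, since that median was -0.00353% and 0% in replicates 1 and 2. It was 1.82% in PANC-1 simvastatin 2 µM replicate 3, which was not set apart. Other handling of reads shared with pseudogenes by the authors' processing is a candidate explanation, since 8 of the 13 genes were pseudogenes, 61.5% against 7.92% of tested genes, a ratio of 7.77. Lower depth cannot be told apart from it, because 2 genes at the library's lowest value had at least 10 FPKM in both other replicates, between the bounds set, and depth is unknown. The library had 140 genes at its lowest value, against at most 41 in another PANC-1 library. Of the 140, 6 had at least 5 FPKM in both other replicates. Its lowest value was 0.131 on the log2 scale, against at most 0.00598 in the other PANC-1 libraries. That value was not particular to this library in the whole table. In MiaPaCa-2 the lowest values ran from 0.0185 (control replicate 2) to 0.131 (lovastatin 2 µM replicate 1). No biological explanation was tested.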

How the results depend on the processing

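The fit of all 42 columns, the fit without 2 PANC-1 libraries and the tests of lists on the difference between the lines were chosen after the data were seen. The sign changed for the Spearman r between the lines at 2 µM without 2 PANC-1 libraries (0.156), and for CXCL8 with fluvastatin at 20 µM in PANC-1, which was at -0.09 and not called, at 0.64 and called without control replicate 3 and without both libraries, and at -0.65 and not called without control replicate 2. Without a call, CXCL8 also changed sign there with lovastatin and simvastatin without control replicate 2 (0.36 to -0.21 and 0.23 to -0.33) and with fluvastatin with a pseudocount of 0.1 (0.04) or without fluvastatin replicate 2 (0.01). The Pearson r at 2 µM was -0.00242 with quantile normalization. Of the named genes, 63 of 377 pairs of gene and contrast lost a call or changed sign with one in at least 1 setting, 41 of them when 1 library was left out. A group left with 1 library was assumed to vary like the other groups. Depth is unknown, so what it limits was not tested. For every count below the cause was not tested, except that fits of 2 groups alone and fits without a library have fewer samples.

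With all 42 columns, MiaPaCa-2 pairs at 2 µM had 68 (simvastatin against lovastatin), 12 (fluvastatin against lovastatin) and 134 (fluvastatin against simvastatin) genes called, against 25, 0 (828 at an unadjusted p under 0.05 in limma) and 48. In these fits the derived columns count as replicates. With 2 groups alone, simvastatin against lovastatin and fluvastatin against simvastatin at 2 µM had 2 and 3, and fluvastatin against lovastatin at 20 µM had 1173 against 2009. PANC-1 at 2 µM against control had 58, 47 and 30 genes against 340, 242 and 342, and its pairs at 2 µM had 1, 7 and 5 against 0 (365 at an unadjusted p under 0.05), 1 and 1. Quantile normalization gave 2 for fluvastatin against lovastatin at 2 µM in MiaPaCa-2.

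The labels give replicate numbers without saying what they share, and residuals did not pair by number. With a block for the replicate number, fluvastatin against simvastatin at 2 µM in MiaPaCa-2 had 30 genes against 48, and fluvastatin against lovastatin at 2 µM in PANC-1 had 2 against 1. The block moved no other count by over 1.5 times.

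Without PANC-1 control replicate 3 and simvastatin 20 µM replicate 3, lovastatin and simvastatin at 2 µM had 378 and 561 genes against 242 and 342. The pairs at 2 µM had 3, 11 and 27, the lines correlated at 2 µM with a Pearson r of 0.221 and a Spearman r of 0.156 against 0.00626 and -0.0123, and 249 against 143 genes were called the same way with all 3 statins. With camera and an estimated correlation, 5 lists were called for fluvastatin and for simvastatin at 2 µM in MiaPaCa-2, against 9 each. In PANC-1 3, 1 and 1 were called at 2 µM against 8, 6 and 5, 10 with fluvastatin and with lovastatin at 20 µM against 17 and 16, and 10 for 20 against 2 µM against 18.

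Leaving out 1 library gave, in MiaPaCa-2 at 2 µM, between 15 and 22 genes for simvastatin against lovastatin, between 0 and 39 for fluvastatin against lovastatin (39 without fluvastatin 2 µM replicate 1) and between 4 and 71 for fluvastatin against simvastatin (4 without fluvastatin 2 µM replicate 3). Fluvastatin against lovastatin at 20 µM had between 1170 (without lovastatin 20 µM replicate 2) and 1669. In PANC-1 at 2 µM the range was 189 (without fluvastatin replicate 3) to 384 for fluvastatin, 125 (without lovastatin replicate 3) to 274 for lovastatin and 226 (without simvastatin replicate 1) to 428 (without control replicate 3) for simvastatin. PANC-1 pairs at 2 µM had between 1 and 2 genes for fluvastatin against lovastatin and between 0 and 2 for fluvastatin against simvastatin (541 at an unadjusted p under 0.05 with all libraries).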

Other observations

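Targets of the liver X receptors, which sense oxysterols and drive sterol efflux, moved both ways and were called as a list with no statin, dose or line (camera adjusted p between 0.358 and 0.934). In MiaPaCa-2 at 20 µM the phospholipid enzyme gene LPCAT3 fell with each statin (log2 fold change -1.17, -1.81 and -1.64 for fluvastatin, lovastatin and simvastatin). In PANC-1 at 20 µM APOE, which carries cholesterol out of cells, rose by 1.63, 1.03 and 1.58, while MYLIP, a ubiquitin ligase gene, fell (-1.33, -1.36 and -1.26). The enzymes that make prenyl groups or use them, for protein prenylation, coenzyme Q and dolichol, were also called as a list nowhere (camera adjusted p between 0.224 and 0.967). Among them, PDSS1, which makes the side chain of coenzyme Q, fell in MiaPaCa-2 at 20 µM (-1.9, -1.42 and -1.11), and DHDDS, which makes dolichol, rose in PANC-1 at 20 µM (1.63, 1.34 and 1.02). LPCAT3, APOE, MYLIP, PDSS1 and DHDDS were chosen after their values were seen.

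Of the cell death genes, BMF differed between statins in both lines at 20 µM and PMAIP1 in MiaPaCa-2. BMF, a death-promoting gene of the BCL2 family, rose with fluvastatin and lovastatin in MiaPaCa-2 (2.73 and 1.42) and with fluvastatin in PANC-1 (1.7). PMAIP1, which encodes NOXA, rose with lovastatin and simvastatin in MiaPaCa-2 (2.76 and 2.02), with fluvastatin at 0 (adjusted p = 0.99), and rose with each statin in PANC-1 (0.85, 0.71 and 0.9). In MiaPaCa-2 fluvastatin exceeded simvastatin by 2.32 for BMF (adjusted p = 1.4e-08) and lay below it by -2.02 for PMAIP1 (adjusted p = 8.4e-10). In PANC-1 fluvastatin exceeded simvastatin by 1.5 for BMF (adjusted p = 9e-04), and no difference between statins in PMAIP1 passed the test. As a list at 20 µM, BCL2 family genes differed for fluvastatin against lovastatin in MiaPaCa-2 (5 of 11 lower, adjusted p = 0.00817) and for no other pair in either line. Common reference genes moved as well. At 20 µM GAPDH fell in both lines (means of -1.12 and -1.25), PGK1 fell in both (-1.22 and -1.14), and ACTB fell with each statin in MiaPaCa-2 and with fluvastatin and simvastatin in PANC-1. PMAIP1 and BMF were chosen as list members with large changes after their values were seen.

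Markers of other cell types had 2 measured genes per type and were not tested as lists. At 2 µM in MiaPaCa-2 RGS5 rose (0.96, 0.92 and 1.06, adjusted p = 1.7e-05, 2.4e-05 and 5.2e-06), as did CD68 (0.82, 0.71 and 0.96, adjusted p = 0.013, 0.024 and 0.0042), and CD14 fell with simvastatin (-0.75, adjusted p = 0.017). At 2 µM in PANC-1 THY1 rose (0.83, 0.77 and 0.64, adjusted p = 0.00066, 0.0018 and 0.0067), and RGS5, CD68 and CD14 passed no test. RGS5 stood at 6.85 on the log2 scale in PANC-1 control replicate 3, against 1.71 and 1.31 in replicates 1 and 2.

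The libraries of the compared groups were also divided in other ways. For 20 against 2 µM, 100 drawn splits of the treated libraries were counted, and 1, the real one, called as many genes in each line (6700 genes with a highest other of 4599 in MiaPaCa-2, and 6385 with 2669 in PANC-1), so a random division of the libraries was excluded as the whole source. The labels do not say that replicates are separate cultures, so a difference between cultures other than the dose was not excluded. For groups of 3 against 3 the 10 splits are too few for a share under 0.05. There the real count and the highest other were 340 and 2, 242 and 3, and 342 and 6 for PANC-1 at 2 µM with fluvastatin, lovastatin and simvastatin, and 5466 and 0, 3993 and 1, and 5130 and 36 at 20 µM. In MiaPaCa-2 at 2 µM they were 25 and 1 for simvastatin against lovastatin, 0 and 1 for fluvastatin against lovastatin (10 of 10 splits called as many; 828 at an unadjusted p under 0.05 in limma) and 48 and 2 for fluvastatin against simvastatin, which had 4795 and 1 at 20 µM. The PANC-1 pairs, in the same order, had 0 and 0 (10 of 10 splits; 365 at an unadjusted p under 0.05), 1 and 0, and 1 and 0 at 2 µM, and 3319 and 0, 2645 and 0, and 4096 and 3 at 20 µM.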
